A study of Homo sapiens with 9 samples.

How the data were processed

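Gene expression was measured by RNA sequencing in 9 primary cultures of human breast fibroblasts, from 3 donors and 3 sites per donor (tumor, adjacent tissue at 1 cm and adjacent tissue at 5 cm). Per the labels' protocols, RNA was taken at passage 2, treated with DNase, depleted of ribosomal RNA and made into libraries with an Ion Torrent total RNA kit. Labels that identify a donor were replaced by replicate numbers, and the same number marks the same donor at every site. Each donor and site had 1 culture, so a difference between sites within a donor includes any difference between cultures.

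Per the submitters' processing notes, the tools were STAR 2.5.1b, featureCounts, HTSeq 0.61p1, R 3.2.2, edgeR 3.12.0 and DESeq 1.22.0 with the genome build GRCh37; the role and order of each are not given in the sources used here, nor is the treatment of strand. The deposited table held 1 value per gene and library for 21044 genes, each with 1 RefSeq transcript. Its values are a score in the sense that they are neither raw reads nor a standard unit: the authors deposited whole numbers whose totals, 9258576 to 9259739, were equal within 0.013%, and low values fell on regular steps that differed between libraries. Values of this kind arise when read counts are multiplied by 1 factor per library and rounded. The step was fitted by likelihood to how often each whole number occurred. It gave the value of 1 read, from 0.612 to 2.36, and from it the depth, 3918000 to 15120000 reads. In libraries where 1 read was worth less than 1 unit, rounding hides whole reads, so reads were not recovered for the tests and no count model was used. Approximate reads, the value divided by the step and rounded, served only to thin the libraries to a common depth. The positions deposited by the authors comprise a start and an end, both of unit other; the end lay about a transcript length after the start, so only chromosomes and starts are printed, in GRCh37. The GRCh38 annotation used here served for gene names, biotypes, transcript lengths and host genes of small RNAs only.

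Genes linked to the Y chromosome or to X inactivation (19) were removed. A gene was tested when its value was at least 10 in at least 3 libraries, which kept 14194 of 21025 genes. Values were used as log2(value + 1), so differences of low genes are understated. Linear models with site and donor terms were fitted to all 9 libraries with limma 3.58.1 (trend method) in R 4.3.3, with 4 residual and 3.29 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were tumor against 5 cm, tumor against 1 cm, 1 cm against 5 cm and tumor against the mean of both adjacent sites, with an F-test over the 3 sites. The plan had been a quasi-likelihood test on counts with limma as its replacement should the values not be counts; the unit required the replacement, and log2(value + 1) took the place of log2 CPM. The median standard error of a pairwise log2 difference was 0.249. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6 for tables.

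The donor is the block because libraries of the same number come from the same donor. Deviations from site means correlated at -0.139 to 0.809 between libraries of a donor (median 0.585, above 0.1 in 7 of 9 pairs) and at -0.725 to 0.271 between donors (median -0.452). The 2 pairs of a donor below 0.1 both held adjacent 5 cm replicate 3.

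The comparisons, their tests, the gene lists and the rule for named genes were chosen before the data were examined, as were the alternatives other than those given with the results as chosen later. The F-test among donors and the simulations with unequal noise were also added later. Of 31 gene lists with 525 entries, 506 entries matched the table, and 29 lists with at least 3 measured members were tested. They covered fibroblast activation, matrix, proteases, basement membrane, signalling (TGF-beta, WNT, growth factors, IGF binding proteins), inflammation, interferon, complement, cell cycle, histones, p53 targets, immediate early genes, hypoxia, cholesterol, the unfolded protein response, oxidative stress, HOX genes, EMT factors, ribosomal and reference genes, and markers of adipocytes, luminal and basal epithelium, endothelium, pericytes, macrophages and lymphocytes. Mitochondrially encoded mRNAs were listed but not measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over 87 tests, and again with an estimated correlation and with fry. The text names up to 10 genes per direction past the threshold that move alike in all 3 donors, filled to 5 by smallest p; up to 4 members per list that pass when adjusted over the list alone, or the 2 of smallest p in a list that passed; and genes chosen in advance, of which 11 are given. Some genes that this rule names are not reported here. Small RNAs, pseudogenes and unnamed loci were counted but not named.

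The place of 1 cm between the other sites was the slope over genes of the 1 cm value minus the mean of tumor and 5 cm on the difference between them, per donor and on the site means. The agreement of tumor and 1 cm differences was set beside 100 simulations with unchanged groups, with equal noise in all libraries and with noise scaled to the residual spread of each. Alternatives covered scaling, filter, pseudocount, weights, the donor term, the libraries in the fit and each donor or library left out.

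The scripts were tested on simulated data with 200 changed genes among 14194, in 5 simulations per contrast. For tumor against 5 cm, 27.6% of genes changed by a fold of 2 were called, 77.6% at 4, 90.8% at 8 and 95.2% at 16, with 9.8 false calls on average. For tumor against 1 cm these were 28.0%, 82.0%, 92.8% and 96.0%, and for 1 cm against 5 cm 27.6%, 82.0%, 93.2% and 96.8%. A list shifted by 0.5 on the log2 scale between tumor and 5 cm passed camera in 17 of 20 simulations, in which genes were independent, and 0 of 87 list tests passed on average with no change. A 1 cm group set to the tumor level gave a mean slope of 0.362 where 0.5 was put in. There every gene had a log2 difference drawn from a standard normal distribution, not matched in size to the data.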

Results

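RNA sequencing of total RNA depleted of ribosomal RNA was used to measure gene expression in 9 primary cultures of human breast fibroblasts, the spindle-shaped cells that make most of the connective tissue matrix. The cultures came from 3 donors with breast tumors. From each donor, fibroblasts were grown from the tumor, from adjacent tissue 1 cm away and from adjacent tissue 5 cm away, and were sequenced at passage 2. Each site therefore had 3 libraries, 1 per donor, and the donors are called replicates 1, 2 and 3. The title of the study speaks of field cancerization, so the comparisons ask how tumor fibroblasts differ from those of the surrounding tissue and whether those at 1 cm resemble the tumor or the more distant site.

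The deposited table gave 21044 genes as read counts scaled to a common total, 9258576 to 9259739 per library. A step per library, fitted to how often each whole number occurred among the low values, put the depth at 3918000 to 15120000 reads, a 3.86-fold range. The adjacent 5 cm library of replicate 3 was the shallowest, with 1 read worth 2.36 units of the scaled value. The 10 most abundant genes took 10.97% to 18.41% of each library. After the filter on low values, 14194 genes were tested.

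The donors differed more than the sites. In replicate 2, POSTN, which encodes the matrix protein periostin, had scaled counts of 94 to 326 over the 3 sites, against 22453 to 42230 in replicate 1. MMP1, the interstitial collagenase, ranged from 24 to 97 in replicate 2 and from 6986 to 9441 in replicate 1. Of the sum of squares over all tested genes, 55.3% went to donor, 15.1% to site and 29.6% to the residual, where unstructured noise would give donor and site 25% each. With 2 donors such noise would give donor 20% and site 40%, and the shares were 34.1% and 32.77% without replicate 2 and 41.7% and 30.52% without replicate 1. A limma F-test on the donor term, added after the values were seen, called 1221 genes, and 3816 without adjacent 5 cm replicate 3. These 1221 were 8.6% of the tested genes and included 13 of the 26 cell cycle genes, 10 of the 20 TGF-beta targets and 8 of the 20 immediate early genes, but 0 of the 18 cholesterol, 21 ribosomal protein and 6 IGF binding protein genes. These shares were not tested.

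Adjacent 5 cm replicate 3 stood apart from the other libraries of its donor. On the first principal component, which held 47.8% of the variance, it lay at 51.2, while the 1 cm and tumor libraries of that donor lay at -44.8 and -36.1. Its POSTN value was 1158, against 22828 at 1 cm and 16660 in the tumor. ACTA2, the smooth muscle actin of myofibroblasts, was at 853 there, against 9232 and 12103. The spread of its residuals was 1.51 times the mean of all libraries, and the next highest library was at 1.07.

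**Figure D1:**
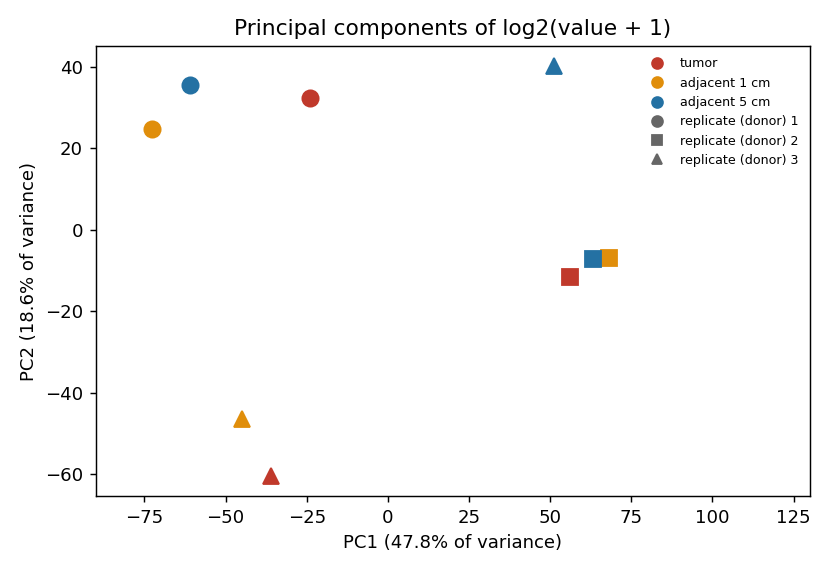
Each point is 1 of the 9 libraries, placed by its scores on the first (x axis, 47.8% of the variance) and second (y axis, 18.6%) principal components of log2(value + 1) over the 14194 tested genes; color gives the site and shape the donor. The 3 libraries of replicate 2 lie together at 56.0 to 68.1 on the x axis, and adjacent 5 cm replicate 3 lies at 51.2, away from the other libraries of its donor.

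**Figure D2:**
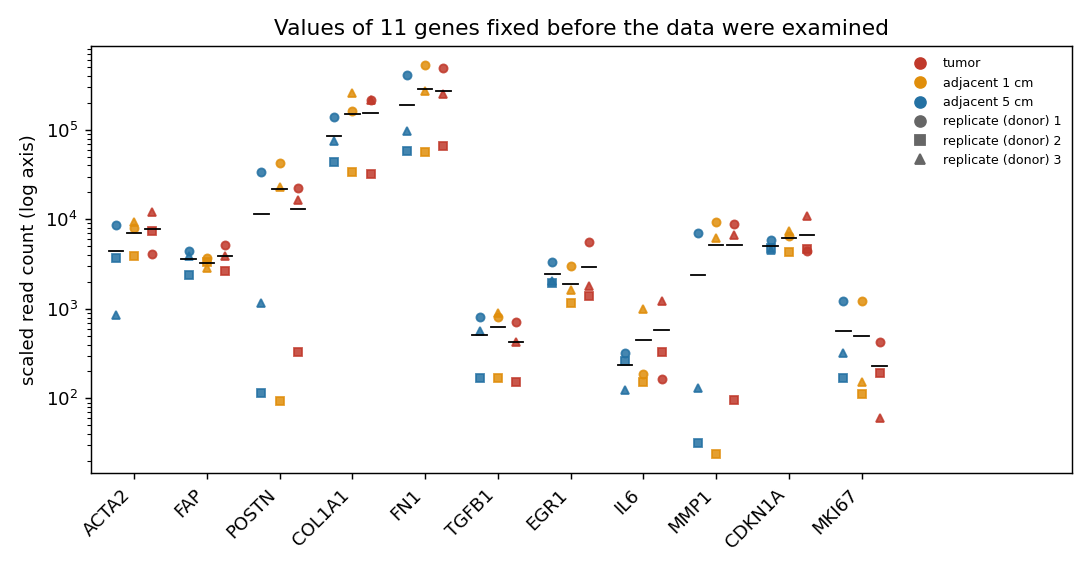
Scaled read counts (log axis) of 11 genes chosen in advance are shown for each library, with color for the site, shape for the donor and a short black line at the arithmetic mean of the 3 libraries of a site. POSTN and MMP1 values in replicate 2 (squares) lie far below those of replicate 1 at every site.

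Tumor fibroblasts had lower cell cycle values than fibroblasts from 5 cm. All 26 cell cycle genes had negative differences, with a median log2 difference of -0.78, and the list fell in the camera test with a preset correlation between genes (adjusted p = 9.35e-10). The call was lost at adjusted p = 0.652 with an estimated correlation. MKI67, the proliferation antigen Ki-67, averaged 572 ± 571 (SD, n = 3) at 5 cm and 228 ± 189 in the tumor, a log2 difference of -1.24 ± 0.49 (SE). TYMS, thymidylate synthase, differed by -1.06 ± 0.32 and MCM2, a part of the replicative helicase, by -0.75 ± 0.26. The list's median was -1.39 in replicate 1 and -1.36 in replicate 3 but 0.26 in replicate 2. Replication-dependent histones, which are made in S phase, fell as well, with 9 of 11 members negative, a median of -0.51 and donor medians of -1.40, -0.081 and -0.60 (camera adjusted p = 0.0253). That call was lost too, at adjusted p = 0.652 with an estimated correlation. Among them, HIST1H2AM differed by -1.16 ± 0.38 and HIST1H1B by -0.82 ± 0.35.

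Extracellular matrix and TGF-beta genes were higher in the tumor cultures than at 5 cm on average, through replicate 3. Of 21 fibrillar collagen and structural matrix genes, 15 were positive, with a median log2 difference of 0.60 (camera adjusted p = 0.00597, but adjusted p = 0.652 with an estimated correlation). COL10A1, a network-forming collagen, differed by 1.19 ± 0.42 (SE, n = 3) and BGN, the proteoglycan biglycan, by 1.21 ± 0.57. Of 20 TGF-beta targets, 15 were positive, with a median of 0.36 (camera adjusted p = 0.000171, but adjusted p = 0.652 with an estimated correlation). LTBP1, which holds latent TGF-beta in the matrix, differed by 0.98 ± 0.28 and JUNB, an AP-1 transcription factor, by 0.59 ± 0.20. The medians in replicates 1, 2 and 3 were 0.41, -0.048 and 1.38 for the matrix list, and -0.17, 0.41 and 1.11 for the TGF-beta targets. Without adjacent 5 cm replicate 3, the library that stood apart, the medians were 0.089 and 0.099, and neither list passed (camera adjusted p = 0.362 and 0.332).

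A further 4 lists passed in this comparison. Of 20 immediate early genes, which respond to stimulation within minutes, 15 were higher in the tumor, with a median log2 difference of 0.26 and donor medians of 0.51, 0.033 and 0.23 (camera adjusted p = 0.00417, but adjusted p = 0.652 with an estimated correlation). IER2, a member of this list, differed by 0.49 ± 0.14 (SE, n = 3). Of 15 genes of the unfolded protein response, 12 were positive, with a median of 0.22 and donor medians of -0.098, 0.14 and 0.49 (camera adjusted p = 0.00864, but adjusted p = 0.652 with an estimated correlation), among them SEL1L at 0.45 ± 0.19 and TRIB3 at 0.75 ± 0.43. Ribosomal protein genes rose slightly, with 18 of 21 positive, a median of 0.12 and donor medians of 0.14, 0.23 and 0.025 (camera adjusted p = 0.0269, but adjusted p = 0.652 with an estimated correlation), RPS4X at 0.51 ± 0.23 and RPLP0 at 0.36 ± 0.22, and the call was also lost without the filter on low values (adjusted p = 0.0641). Cholesterol biosynthesis genes fell, with 17 of 18 negative, a median of -0.40 and donor medians of -0.064, -0.080 and -1.06 (camera adjusted p = 0.004), and this call was lost at adjusted p = 0.655 with an estimated correlation. Its members of smallest p were LSS, lanosterol synthase, at -0.48 ± 0.26 and SC5D, a sterol desaturase that went against the list, at 0.29 ± 0.15. Without adjacent 5 cm replicate 3, camera passed the immediate early genes (median 0.16, adjusted p = 0.044), the cell cycle genes (-0.61, adjusted p = 7.26e-08) and the histones (-0.70, adjusted p = 0.00112). It did not pass the unfolded protein response (0.025, adjusted p = 0.784), the ribosomal proteins (0.13, adjusted p = 0.157) or cholesterol biosynthesis (0.015, adjusted p = 0.873). The median had 1 sign in all 3 donors for 4 of the 8 lists that passed.

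No gene passed limma's threshold of adjusted p under 0.05 between tumor and 5 cm. The smallest adjusted p from limma was 0.577, and 681 genes had an unadjusted p under 0.05 (297 higher in the tumor, 384 lower) where 710 were expected by chance. The latter count depended on single libraries, at 1463 without adjacent 5 cm replicate 1, 1222 without adjacent 5 cm replicate 2 and 314 without tumor replicate 3. Array weights and vooma weights, both added later, also called 0 genes, with 316 and 751 at an unadjusted p under 0.05. The genes named next are those of smallest unadjusted p that went the same way in all 3 donors, and none of them passed. MGP, matrix Gla protein, an inhibitor of calcification (chromosome 12, start 15034114 in GRCh37), averaged 997 ± 807 (SD, n = 3) at 5 cm and 2420 ± 1817 in the tumor, a log2 difference of 1.63 ± 0.27 (SE, limma adjusted p = 0.874). LDLRAD4, a negative regulator of TGF-beta signalling, differed by 2.04 ± 0.38, and RARB, retinoic acid receptor beta, by 1.17 ± 0.22. ZNF853 differed by 1.34 ± 0.26 and PRKAR1B, a regulatory subunit of protein kinase A, by 0.93 ± 0.18. On the lower side, AK5, an adenylate kinase, differed by -1.43 ± 0.25, ABI3BP, an extracellular matrix protein, by -1.14 ± 0.22 and ANPEP, aminopeptidase N, by -1.63 ± 0.35. GFRA1, a receptor for the neurotrophic factor GDNF, differed by -1.43 ± 0.31 and LINC-PINT, a long noncoding RNA, by -0.89 ± 0.20.

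Of the WNT signalling genes, 2 of 17 passed when adjusted over the list alone. FZD7, a WNT receptor, differed by 0.72 ± 0.16 (SE) between tumor and 5 cm and WISP1, a secreted WNT target, by 1.70 ± 0.41, each positive in all 3 donors (n = 3, limma adjusted p = 0.0326 over the list and 0.909 over all genes). The list itself did not pass (camera adjusted p = 0.129), and its median of -0.11 had another sign than its mean of 0.098. In the other 28 lists, 0 genes passed when adjusted over the list alone. Of the genes chosen in advance, ACTA2 differed by 1.26 ± 0.83, POSTN by 1.59 ± 0.91 and MMP1 by 2.53 ± 1.09. In each of these 3, the difference in replicate 3 was 3.83 or more. The others were COL1A1 at 0.57 ± 0.52, FN1 (fibronectin) at 0.60 ± 0.51, IL6 at 0.87 ± 0.79, FAP (fibroblast activation protein) at 0.13 ± 0.22, CDKN1A (the p21 cell cycle inhibitor) at 0.28 ± 0.32, TGFB1 at -0.24 ± 0.21 and EGR1 at 0.043 ± 0.24.

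The remaining lists did not pass camera between tumor and 5 cm. Inflammatory cytokines and chemokines had the smallest adjusted p of these, 0.104, with a median log2 difference of 0.50 and donor medians of -0.51, -0.20 and 2.74. Luminal epithelial markers had a median of 0.83 (adjusted p = 0.197) and donor medians of -0.36, 0.095 and 3.26, basal and myoepithelial markers 0.23 (adjusted p = 0.125) and pericyte and smooth muscle markers 0.29 (adjusted p = 0.481). The interferon response had -0.14 (adjusted p = 0.547), complement -0.21 (adjusted p = 0.807) and macrophage and myeloid markers 0.15 (adjusted p = 0.763). Myofibroblast and CAF (cancer-associated fibroblast) activation genes had a median log2 difference of 0.47 (adjusted p = 0.16), with donor medians of -0.57, 0.26 and 1.39. Matrix proteases, inhibitors and crosslinking enzymes had 0.14 (adjusted p = 0.16), basement membrane genes 0.021 (adjusted p = 0.822) and IGF binding proteins 0.28 (adjusted p = 0.819). Growth factors and receptors had a median of 0.17 (adjusted p = 0.632), p53 targets and senescence genes 0.15 (adjusted p = 0.125), and hypoxia and glycolysis genes -0.20 (adjusted p = 0.449). HOX genes, which mark the position of a cell in the body, had -0.096 (adjusted p = 0.806). The medians of EMT transcription factors and cadherins (-0.096, adjusted p = 0.513), of the oxidative stress response (0.22, adjusted p = 0.157) and of adipocyte markers (0.030, adjusted p = 0.385) had another sign than their means. Endothelial markers had -1.26 over 5 genes (adjusted p = 0.891) and reference genes -0.11 (adjusted p = 0.806). Of the lymphocyte markers only 2 of 12 and of the mitochondrially encoded mRNAs 0 of 13 were measured above the filter, so neither list was tested.

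Immediate early genes were higher in tumor fibroblasts than in those from 1 cm in every donor. Of 20 members, 17 were positive, with a median log2 difference of 0.46 and donor medians of 0.56, 0.45 and 0.34, and the list rose by camera (adjusted p = 3.25e-10). It was lost at adjusted p = 0.277 with an estimated correlation, where its unadjusted p was 0.00319. IER2 averaged 906 ± 208 (SD, n = 3) at 1 cm and 1360 ± 262 in the tumor, a log2 difference of 0.60 ± 0.14 (SE). DUSP1, a phosphatase that switches off MAP kinases, differed by 0.50 ± 0.15 and EGR1, an early response transcription factor, by 0.46 ± 0.24. The list passed camera with the preset correlation without each donor in turn and without adjacent 5 cm replicate 3 (adjusted p = 1.46e-10). The latter fit keeps the tumor and 1 cm libraries of every donor. It can change the estimated spread but not the differences, so it adds little. Leaving out adjacent 1 cm replicates 1 and 3 leaves 1 library at 1 cm, too few to decide whether the call depends on them.

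Basal and myoepithelial markers were lower in the tumor cultures than at 1 cm, where adjacent 1 cm replicates 1 and 3 carried basal keratins. All 11 members were negative, with a median log2 difference of -1.87 (camera adjusted p = 2.86e-09), lost at adjusted p = 0.652 with an estimated correlation. KRT17 read 1386 and 739 in those 2 libraries, and 0 to 189 in the other 7. ITGB4, an integrin of epithelial anchoring junctions, differed by -2.70 ± 0.92 (SE, n = 3). The medians in replicates 1, 2 and 3 were -5.11, 0.17 and -1.85. Pericyte and smooth muscle markers fell along with them, with 9 of 11 negative, a median of -0.26 and donor medians of -1.51, 0.31 and -0.39 (camera adjusted p = 0.00597, but adjusted p = 0.652 with an estimated correlation). ACTG2, an enteric smooth muscle actin, differed by -3.09 ± 1.28 and SMTN, smoothelin, by -0.47 ± 0.26. Without adjacent 1 cm replicates 1 and 3, the medians of both lists were positive, at 0.075 and 0.11. That fit holds 1 library at 1 cm, from replicate 2.

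Cell cycle genes were also lower in the tumor than at 1 cm, with 25 of 26 negative and a median of -0.40. The donor medians were -0.98, 0.42 and -0.77 (camera adjusted p = 1.64e-09, but adjusted p = 0.652 with an estimated correlation). The tumor libraries are the same 3 as in the comparison with 5 cm, so this is not an independent repeat of it. E2F1, a transcription factor of the G1 to S transition, differed by -0.79 ± 0.35 (SE, n = 3) and CENPE, a kinetochore motor, by -0.68 ± 0.36. Of 12 complement genes 9 were higher, with a median of 0.55 and donor medians of 1.25, -0.11 and 0.46 (camera adjusted p = 0.00248, but adjusted p = 0.652 with an estimated correlation), CFB at 0.85 ± 0.28 and C3 at 1.24 ± 0.70. Of 18 inflammatory cytokines and chemokines 17 were higher, with a median of 0.37 and donor medians of -0.11, 0.56 and 1.08 (camera adjusted p = 0.0253, but adjusted p = 0.652 with an estimated correlation), IL33 at 1.14 ± 0.57 and CXCL2 at 1.3 ± 0.73. Of 6 macrophage and myeloid markers 5 were higher, with a median of 0.92 and donor medians of 1.97, 0.48 and -0.095 (camera adjusted p = 0.00597, but adjusted p = 0.652 with an estimated correlation), among them CD14 at 1.43 ± 0.60 and CD74, the invariant chain of MHC class II, at 1.36 ± 0.72. Without adjacent 1 cm replicates 1 and 3, the medians were 0.43 for the cytokines and 0.82 for the macrophage markers. They were -0.14 for cell cycle and -0.097 for complement. That fit holds 1 library at 1 cm, from replicate 2, and draws on tumor and 5 cm libraries of other donors. Its macrophage and cell cycle medians thus differ from the 0.48 and 0.42 within replicate 2. The median had 1 sign in all 3 donors for 1 of the 7 lists, the immediate early genes. Of the 22 lists that did not pass, the interferon response had the smallest camera adjusted p, 0.0531, and it passed with median-ratio scaling (adjusted p = 0.0327).

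No single gene passed between tumor and 1 cm, where the smallest limma adjusted p was 1. With limma, 181 genes had an unadjusted p under 0.05 (134 higher, 47 lower) against 710 expected by chance, and array weights and vooma weights called 0 genes as well, with 612 and 229 at that p. The 181 became 415 without adjacent 5 cm replicate 3, 279 without tumor replicate 2, 272 and 80 without adjacent 1 cm replicates 2 and 1, and 342 and 69 without every library of replicate 3 and of replicate 1. No member of any list passed when adjusted over the list alone. The genes of smallest unadjusted p with 1 direction in all 3 donors are given as values that did not pass. Higher in the tumor were IER2, JAKMIP2 (1.28 ± 0.31, SE, n = 3), IQGAP2 (2.17 ± 0.56), the nuclear receptor NR4A3 (0.99 ± 0.28), itself induced early after stimulation, and SMPDL3A (1.06 ± 0.31). Lower were NTN4, the basement membrane protein netrin-4 (-0.82 ± 0.19), GALNT3, a mucin-type glycosyltransferase (-1.80 ± 0.45), FOXL1 (-0.93 ± 0.24), CELSR1, a planar cell polarity cadherin (-1.19 ± 0.30), and ACTA1, skeletal muscle actin (-3.68 ± 0.97). ACTA1 read 210 and 19 in adjacent 1 cm replicates 1 and 3, the libraries with basal keratins, and 3 or less in the tumor libraries. In the same libraries CELSR1 read 282 and 415 and GALNT3 60 and 19, against 64 and 12 in adjacent 1 cm replicate 2. NTN4 went the other way, at 145 and 421 against 606. In adjacent 5 cm replicate 1, GALNT3 read 32 and ACTA1 18. Some of these values are low. GALNT3 read 8, 5 and 6 in the tumor libraries of replicates 1, 2 and 3, and IQGAP2 read 2, 12 and 2 at 1 cm and 20, 31 and 15 in the tumor. Of the genes chosen in advance, MKI67 differed by -0.69 ± 0.49, MMP1 by 0.66 ± 1.09, TGFB1 by -0.47 ± 0.21, IL6 by 0.41 ± 0.79 and FAP by 0.20 ± 0.22. The others were ACTA2 at 0.13 ± 0.83, POSTN at 0.14 ± 0.91, COL1A1 at 0.031 ± 0.52, CDKN1A at 0.030 ± 0.32 and FN1 at 0.0093 ± 0.51, the last turning to -0.018 with median-ratio scaling.

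Between the adjacent sites, basal and myoepithelial markers were higher at 1 cm than at 5 cm. All 11 members were positive, with a median log2 difference of 2.30 and donor medians of 2.63, 0 and 3.84, and the list rose by camera (adjusted p = 1.64e-09), a call lost at adjusted p = 0.652 with an estimated correlation. ITGB4 averaged 59.7 ± 70.6 (SD, n = 3) at 5 cm and 468 ± 428 at 1 cm, a log2 difference of 2.93 ± 0.92 (SE). Of 8 luminal epithelial markers 5 were higher, with a median of 1.37 and donor medians of 0.25, -0.031 and 3.58 (camera adjusted p = 0.0303, but adjusted p = 0.652 with an estimated correlation), KRT8 at 2.20 ± 0.90 and KRT7 at 2.14 ± 1.16, and the call was also lost with median-ratio scaling (adjusted p = 0.0793). Of 11 pericyte and smooth muscle markers 8 were higher, with a median of 0.85 and donor medians of 0.28, 0.21 and 2.02 (camera adjusted p = 0.00597, but adjusted p = 0.652 with an estimated correlation), NOTCH3 at 1.42 ± 0.57 and ACTG2 at 2.94 ± 1.28. Without adjacent 1 cm replicates 1 and 3, 1 library is left at 1 cm. The medians were then 0.033 (basal), -0.0061 (luminal) and 0.069 (pericyte). Without adjacent 5 cm replicate 3, camera passed the basal list (1.24, adjusted p = 1.43e-05) and not the luminal (0.35, adjusted p = 0.362) or the pericyte list (0.18, adjusted p = 0.0977).

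Matrix and TGF-beta genes were also higher at 1 cm than at 5 cm. Of 21 matrix genes 16 were positive, with a median log2 difference of 0.59 and donor medians of 0.21, 0.079 and 1.65 (camera adjusted p = 0.000134, but adjusted p = 0.652 with an estimated correlation). COL10A1 differed by 1.35 ± 0.42 (SE, n = 3) and COL5A1, which nucleates collagen fibrils, by 0.89 ± 0.37. Of 20 TGF-beta targets 19 were positive, with a median of 0.33 and donor medians of 0.074, 0.058 and 1.07 (camera adjusted p = 1.93e-06, but adjusted p = 0.652 with an estimated correlation). PMEPA1, a TGF-beta-induced inhibitor of SMAD signalling, differed by 1.05 ± 0.24 and LTBP1 by 0.97 ± 0.28. Without adjacent 5 cm replicate 3, camera passed the matrix list at a median of 0.18 (adjusted p = 0.0124) and the TGF-beta targets at 0.18 (adjusted p = 0.0069). Without adjacent 1 cm replicates 1 and 3, which leaves 1 library at 1 cm, the medians were 0.15 and 0.031.

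Complement, interferon, cholesterol and cell cycle genes were lower at 1 cm than at 5 cm, and the unfolded protein response was higher. Of 12 complement genes 11 were negative, with a median log2 difference of -0.80 and donor medians of -0.26, 0.21 and -2.38 (camera adjusted p = 0.0106, but adjusted p = 0.652 with an estimated correlation). CFB differed by -0.77 ± 0.28 (SE, n = 3). Of 15 genes of the unfolded protein response 13 were positive, with a median of 0.18 and donor medians of -0.019, 0.27 and 0.43 (camera adjusted p = 0.000566, but adjusted p = 0.652 with an estimated correlation), SEL1L at 0.46 ± 0.19 and TRIB3 at 0.80 ± 0.43. Cholesterol genes had 17 of 18 members negative, a median of -0.38 and donor medians of -0.014, -0.018 and -1.15 (camera adjusted p = 0.00205, but adjusted p = 0.655 with an estimated correlation), MVD at -0.54 ± 0.24 and MVK at -0.67 ± 0.31. Interferon response genes had 18 of 19 negative, a median of -0.35 and donor medians of -0.049, -0.25 and -0.76 (camera adjusted p = 0.0365, but adjusted p = 0.687 with an estimated correlation), MX2 at -1.61 ± 0.86 and OAS3 at -0.81 ± 0.53, and the call was also lost without the filter on low values (adjusted p = 0.0792). The 26 cell cycle genes were all negative, with a median of -0.26 and donor medians of -0.36, -0.14 and -0.48 (camera adjusted p = 0.0321, but adjusted p = 0.719 with an estimated correlation), TYMS at -0.65 ± 0.32 and MCM3 at -0.38 ± 0.21. Without adjacent 5 cm replicate 3, camera passed none of these 5 lists, with medians of -0.024 for complement (adjusted p = 0.442), -0.014 for interferon and -0.010 for cholesterol (both adjusted p = 0.873), -0.14 for cell cycle (adjusted p = 0.254) and 0.088 for the unfolded protein response (adjusted p = 0.296). Without adjacent 1 cm replicates 1 and 3, the medians were -0.57 for cell cycle and 0.34 for the unfolded protein response. They were 0.066 for complement, -0.17 for interferon and -0.21 for cholesterol. That fit holds 1 library at 1 cm, from replicate 2, and draws on tumor and 5 cm libraries of other donors. Its cell cycle median thus differs from the -0.14 within replicate 2.

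No gene passed limma between 1 cm and 5 cm, where the smallest adjusted p was 0.864. With limma, 537 genes had an unadjusted p under 0.05 (171 higher at 1 cm, 366 lower) against 710 expected by chance, and array weights and vooma weights called 0 genes, with 317 and 549 at that p. The 537 became 1470 and 1186 without adjacent 5 cm replicates 1 and 2, 342 and 186 without adjacent 1 cm replicates 1 and 3, and 305 without every library of replicate 3. Adjusted over the list alone, 1 member of 1 list passed. This was CD36, a fatty acid transporter among the adipocyte markers, which averaged 226 ± 179 (SD, n = 3) at 5 cm and 90.0 ± 134 at 1 cm, a log2 difference of -2.50 ± 0.55 (SE) that was negative in all 3 donors (limma adjusted p = 0.0214 over the list and 0.864 over all genes). Its list did not pass camera (median -0.46, adjusted p = 0.0734), except with median-ratio scaling (adjusted p = 0.0216). The other genes of smallest unadjusted p with 1 direction in all 3 donors did not pass either. They were, on the higher side, VANGL2, a planar cell polarity protein (1.23 ± 0.24), KANK4 (3.41 ± 0.70), B4GALNT4 (2.87 ± 0.61), S100A2 (2.17 ± 0.46) and LRRC17 (1.17 ± 0.26). At 5 cm, KANK4 read 15, 0 and 2, B4GALNT4 10, 3 and 0 and S100A2 22, 4 and 9 in replicates 1, 2 and 3. These values are low. At 1 cm, KANK4 (117, 5 and 80) and S100A2 (73, 14 and 93) were highest in replicates 1 and 3, the libraries with basal keratins. B4GALNT4 (35, 23 and 19) was not. On the lower side were CKB, brain-type creatine kinase (-1.32 ± 0.28), SLC9A5, a sodium-proton exchanger (-1.19 ± 0.26), LINC-PINT (-0.90 ± 0.20) and RBPMS, an RNA-binding protein (-0.66 ± 0.15).

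Among the genes chosen in advance, the differences between 1 cm and 5 cm were 1.13 ± 0.83 (SE, n = 3) for ACTA2, 1.45 ± 0.91 for POSTN and 1.86 ± 1.09 for MMP1. They were 0.54 ± 0.52 for COL1A1, 0.59 ± 0.51 for FN1, 0.47 ± 0.79 for IL6, 0.25 ± 0.32 for CDKN1A and 0.23 ± 0.21 for TGFB1. They were negative for MKI67 at -0.56 ± 0.49, EGR1 at -0.41 ± 0.24 and FAP at -0.072 ± 0.22, the last turning to 0.0037 with median-ratio scaling. The median of a list had 1 sign in all 3 donors for 6 of the 10 lists that passed. Over the 3 comparisons, median, mean and test differed in sign for 4, 4 and 7 lists, none of which passed.

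**Figure D3:**
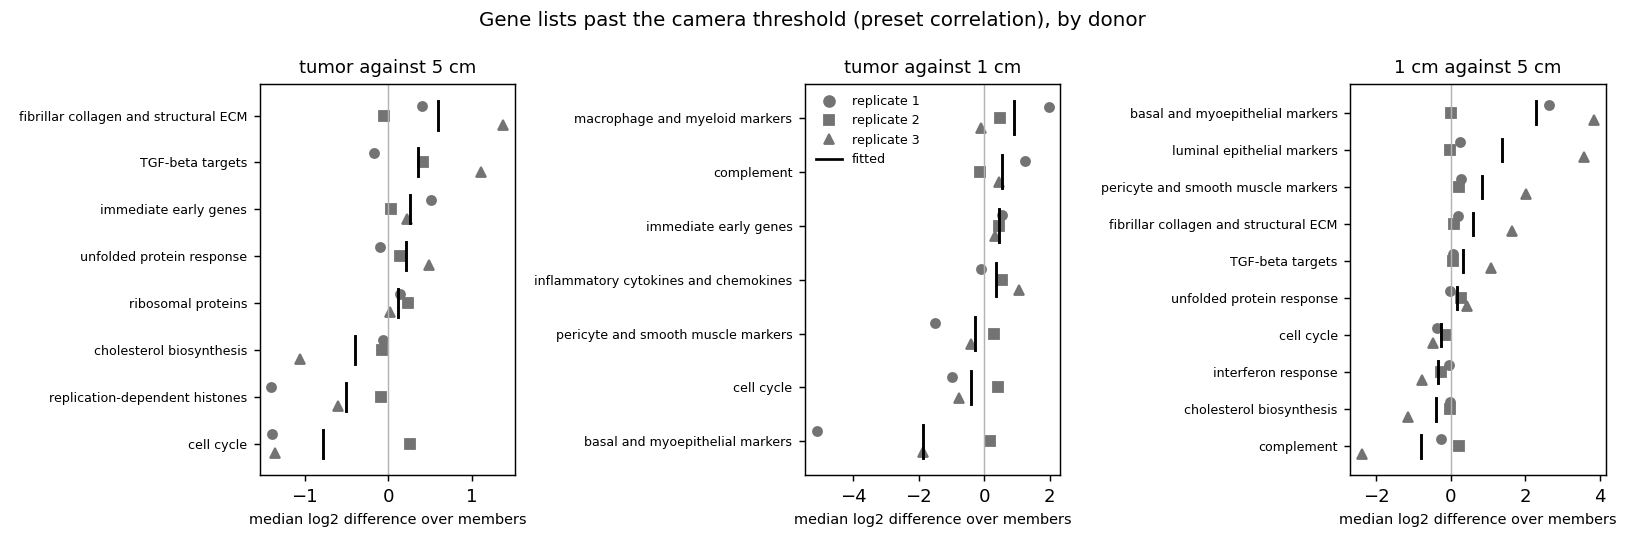
For each gene list past the camera threshold with the preset correlation, symbols give the median log2 difference over the list's members within each donor and the black line the median of the fitted differences (x axis); the panels show tumor against 5 cm, tumor against 1 cm and 1 cm against 5 cm. The immediate early genes in the middle panel lie between 0.34 and 0.56 in the 3 donors, while matrix genes against 5 cm reach 1.38 and 1.65 in replicate 3 only.

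Setting the tumor against the mean of both adjacent sites, limma called 0 of 14194 genes (smallest adjusted p = 0.445), with 348 at an unadjusted p under 0.05, 198 higher and 150 lower. The limma F-test for any difference among the 3 sites called 0 genes as well (smallest adjusted p = 1), with 410 at an unadjusted p under 0.05. Array weights and vooma weights called 0 genes in both. The 348 became 532, 580 and 602 without adjacent 5 cm replicates 1, 2 and 3 and 175 without adjacent 1 cm replicate 1, and the 410 became 853 and 738 without adjacent 5 cm replicates 1 and 2 and 270 without adjacent 1 cm replicate 3. Against the mean of both adjacent sites, MKI67 differed by -0.96 ± 0.42 (SE, limma adjusted p = 1.00).

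The place of the 1 cm cultures between the other sites went different ways in the 3 donors. Without noise, a slope over genes of 0.5 would put the 1 cm cultures at the tumor level and -0.5 at the 5 cm level. With simulated noise, a 1 cm group set to the tumor level gave a mean slope of 0.362. That simulation gave every gene a log2 difference drawn from a standard normal distribution, not matched in size to these data. The slope recovered depends on that size, so 0.362 is no level to hold the observed slopes against. The slopes were -0.27 in replicate 1, 0.20 in replicate 2 and 0.38 in replicate 3, with a mean of 0.10 ± 0.33 (SD, n = 3). An exact two-sided sign-flip test gave p = 0.75, where 3 donors allow no p below 0.25. With unchanged groups whose libraries were as noisy as these, 100 simulations gave a mean slope of 0.10, from 0.084 to 0.12. The slope fitted to the site means, in which donors with larger differences weigh more, was 0.29, above the 0.079 to 0.15 (mean 0.11) of the same simulations. These simulations drew genes independently, so their ranges are narrower than correlated genes would give. A slope above the range therefore decides nothing about the place of 1 cm. Without replicate 3 the mean slope was -0.034 and the slope on site means -0.042.

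Across genes, which are not independent replicates, the tumor and 1 cm differences against the shared 5 cm libraries correlated at Pearson's r = 0.767. Unchanged groups set against the same libraries gave r = 0.50 (0.455 to 0.533) in 100 simulations, or 0.649 (0.617 to 0.685) when each library was as noisy as its residuals. The covariance was 0.186 against a simulated 0.0991 (0.0888 to 0.109) with equal noise, a difference of 0.0866, and against 0.143 (0.129 to 0.163) with unequal noise, a difference of 0.0432. With 3 libraries at 5 cm these could not be split, so part of the excess may come from the shared libraries. Genes were drawn independently here too, so the simulated ranges are too narrow to judge the excess. Without replicate 3, r was 0.534.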

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

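Vooma and array weights, the pseudocounts 0.5 and 8 for gene counts, the filter at 50, the robust variance prior and the fits of lists without adjacent 5 cm replicate 3 or without adjacent 1 cm replicates 1 and 3 were chosen after the data were seen; the other settings here were set beforehand. Limma called 0 genes in each alternative run for gene counts, which leave out the fit without adjacent 1 cm replicates 1 and 3, made for lists only, with 203 to 1463 genes at an unadjusted p under 0.05 for tumor against 5 cm, 37 to 612 for tumor against 1 cm and 164 to 1470 for 1 cm against 5 cm. The smallest adjusted p over the alternatives was 0.055, 0.133 and 0.0501; the first and last came without adjacent 5 cm replicate 2. For tumor against both adjacent sites the counts at unadjusted p were 66 to 602 (smallest adjusted p 0.12) and for the F-test 95 to 853 (0.0928). Without the replicate block the counts were 0 (203, 37, 164, 66 and 95 at an unadjusted p under 0.05), and 6, 6 and 8 lists passed. Median-ratio scaling moved the median of all genes by 0.048, -0.027 and 0.075. A filter at 1 CPM kept the same genes and tests nothing. DESeq2, limma-voom, glmTreat and the glmQLFit setting need counts and were not run.

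The lists depend on the set test. In tumor against 5 cm, tumor against 1 cm and 1 cm against 5 cm, 8, 7 and 10 passed camera with the preset correlation, 0, 0 and 0 with an estimated correlation (up to 0.673 in place of 0.01), and 0, 0 and 0 with fry. Leaving out a donor or adjacent 5 cm replicate 3 gave 4 to 9 lists for tumor against 1 cm. A fit without adjacent 1 cm replicates 1 and 3 leaves 1 library at 1 cm, assumed to vary like the other sites. Only medians are therefore given for it. Of the 25 calls, 19 passed without the block and 13 without adjacent 5 cm replicate 3. Without replicates 1, 2 and 3, 15, 23 and 11 passed.

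Medians turned sign without adjacent 1 cm replicates 1 and 3 for complement (-0.097), basal (0.075) and pericyte (0.11) lists in tumor against 1 cm, and for complement (0.066) and luminal (-0.0061) lists in 1 cm against 5 cm. With replicates or adjacent 5 cm replicate 3 left out, the cholesterol median of tumor against 5 cm ran from -0.593 to 0.015. The cause was not tested beyond the smaller number of libraries.

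Leaving out each donor moved the donor share from 34.1% to 68.69%, the site share from 14.84% to 32.77%, the agreement of tumor and 1 cm differences from 0.534 to 0.881, the mean slope of 1 cm from -0.034 to 0.29 and its slope on site means from -0.042 to 0.33. Among 550 values of named genes under alternatives 17 turned sign, none of which had passed. Over left-out donors, tumor against 5 cm ran from -0.026 to 2.42 for ACTA2, -0.313 to 0.295 for EGR1, -0.336 to 1.80 for IL6 and -0.215 to 0.613 for CDKN1A. Tumor against 1 cm ran from -0.277 to 0.669 for ACTA2, -0.683 to 0.664 for POSTN, -0.172 to 0.181 for COL1A1, -0.097 to 0.065 for FN1 and -0.226 to 0.325 for CDKN1A. For 1 cm against 5 cm the ranges were -0.027 to 1.76 for ACTA2, -0.351 to 0.112 for FAP, -0.082 to 1.00 for COL1A1 and -0.793 to 1.1 for IL6. Median-ratio scaling turned FN1 in tumor against 1 cm to -0.018 and FAP in 1 cm against 5 cm to 0.0037. Depth limits mainly adjacent 5 cm replicate 3, where 1 read is worth 2.36 units.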

Other observations

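The tests of other short noncoding RNAs and of epithelial cells were chosen after the result was seen; the other tests below were written down before it. Apart from its scale, adjacent 5 cm replicate 3 had a profile of its own against the mean of the tumor and 1 cm libraries of its donor. Complement genes were higher in it by a median log2 difference of 2.10 over 12 genes, cholesterol genes by 1.13 over 18, cell cycle genes by 0.97 over 26 and interferon genes by 0.70 over 19. Myofibroblast genes were lower, at -1.62 over 19 genes, as were matrix genes at -1.50 over 21, inflammatory cytokines at -1.59 over 18 and basal epithelial markers at -2.86 over 11. These are values of 1 library and carry no test.

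That library's residual spread was 1.51 times the mean of all libraries. Its shallow depth is argued against as the whole cause, since thinning every library to 3918000 reads left the ratio at 1.40 over 20 thinnings, and it was 1.64 over the 3350 genes with a mean of at least 500. The ratio was also 1.51 after median-ratio scaling, but 1 factor per library moves all its genes alike and leaves their spread as it is, so this test had one possible outcome and decides nothing about the scaling. Over the tested genes this library correlated at 0.916, 0.923 and 0.915 with the 1 cm, 5 cm and tumor libraries of replicate 2. With the 1 cm and tumor libraries of its own donor it correlated at 0.875 and 0.870. Other pairs of libraries from a donor lay at 0.955 to 0.983. Its donor is known from the labels only and was not tested. A biological difference of this culture at 5 cm stays open and was not tested, because no other library has the same donor and site.

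H/ACA small nucleolar RNAs, which guide pseudouridylation of ribosomal RNA, were higher in the tumor than at 5 cm for 76 of 76 measured, with a median log2 difference of 1.14 (0.917, 1.78 and 0.221 by donor) and 38 at an unadjusted p under 0.05, and higher than at 1 cm for 76 of 76, with a median of 0.913. A matching rise of host gene RNA is argued against, since the 50 hosts measured for 65 of the 76 had a median of 0.0421 and an upper quartile of 0.154. These are levels of RNA and not rates, so a change in transcription of the hosts is not excluded. On recovery of short RNAs in library preparation the values are mixed. For 14 other noncoding RNAs of 100 to 220 bases the median was 0.836, and 0.755 against 1 cm. Against each gene's mean over libraries, their log2 medians at 1 cm, 5 cm and tumor were -1.4, -1 and -0.09 in replicate 1. H/ACA had -1.39, -1.14 and -0.16 there. In replicate 2 the values were 0.303, 0.115 and 1.04 against 0.498, -0.454 and 1.48 for H/ACA. In replicate 3 they were -0.0221, 0.396 and 0.707 against 0.153, 0.383 and 0.698. Apart from replicate 2, both classes ran close together. In tumor against 5 cm, 13 longer ones had a median of 0.0586. The 52 microRNA genes had 0.056, but whether their reads came from mature microRNAs or longer precursors was not known. That value therefore does not decide on recovery. The 152 C/D small nucleolar RNAs had a median of 0.898 with 144 positive, yet donor medians of 1.58, 1.65 and -0.548. The written rule for recovery, a median of the 14 RNAs of at least 1/2 of the H/ACA median, was met. Recovery was left open because 2 further conditions were not met. These were positive C/D medians in every donor and microRNA genes at 1/2 of the H/ACA median or more. Stability or processing of these RNAs in tumor fibroblasts also stays open and was not tested.

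Basal keratins stood out in adjacent 1 cm replicates 1 and 3, with KRT17 at 1386 and 739, KRT5 at 689 and 353 and KRT14 at 172 and 133, and KRT5 per KRT17, at 0.497 and 0.478 there, was also 0.503 in adjacent 5 cm replicate 1 and 0.558 in tumor replicate 3, where KRT17 was at 189 and 113. Epithelial cells in the cultures may be the source, but the test did not decide this: the log2 excess above the same donor's other libraries correlated across genes at r = 0.805 between the donors, over the 10 of 11 basal genes with an excess in both. That choice left out LAMA3, whose excess was -75.5 in replicate 1 and 209 in replicate 3, and over all 11 genes Spearman's rho of the excess was 0.7. CDH1 was at 74 and 72 there and 25 or less elsewhere, while EPCAM was at 2 or less in every library and KRT19, at 203 and 143, did not stand out. EPCAM and KRT19 were listed as luminal markers, so their values do not speak against basal cells. Outside the basal list, CDH3 was at 181 and 109 there and 31 or less elsewhere. ACTG2 was at 687 and 402 against 162 or less. MYH11, at 189 and 320, and OXTR, at 403 and 728, did not stand out, with 617 and 748 in tumor replicate 3. Of the 11 basal genes, 5 had a mean of at least 10 in replicate 2 as well, where KRT17 was at 2 or less. Part of the list was thus expressed in cultures nearly free of KRT17, though the cells that express it were not identified. Expression of these genes by the fibroblasts themselves at 1 cm stays open and was not tested.

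Other splits of the libraries were compared with the real ones. For genes they carry no information on chance, since every split gives at least the real count of 0. These were 10 of 10 splits in each pairwise comparison (highest other 1, 1 and 0), 81 of the 81 that could be fitted for tumor against both adjacent sites (highest other 1) and 100 of 100 drawn for the F-test (highest other 24). For lists the real counts of 8, 7 and 10 were reached by 7, 7 and 5 of 10 splits, with highest others of 18, 16 and 15; 10 splits are too few for a share under 0.05. The splits that kept 1 library per donor on each side gave at most 11, 8 and 12. Of these 4 splits per comparison, the real one included, 4, 3 and 3 gave at least as many lists as the real one. Over the 3 comparisons together 25 lists passed, and 50 of 100 drawn splits gave as many (highest other 44), so chance cannot be excluded for the number of lists. Of the 36 splits that kept donors balanced, the real one included, 16 gave as many, with a median of 24 lists and a range of 13 to 39.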
